A study of Arabidopsis thaliana with 9 samples.

How the data were processed

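Whole seedlings of 3 genotypes in the Landsberg erecta accession were compared on Affymetrix arrays, with 3 independent biological samples each of wild type, ebs and shl-2. Per the labels' protocols, plants grew for 18 days in short days, RNA was extracted from complete plants, biotin-labelled cRNA was made from 500 ng of total RNA with a 3' labelling kit, and each sample was hybridized to its own array. The deposited values are log2 signals per probe set, made by the authors with RMA in the affy package per the submitters' processing notes. RMA corrects the background of each array, brings all arrays to a common distribution of probe signals and summarises the probes of a set. The package version and any filtering are not given in the sources used here. The values carried 2 decimals. Scanner files were not used here, so the background correction and the probe-level normalization could not be varied. No array pair held identical values (0 identical pairs among the 9 arrays). Labels describe the samples as independent biological pools, and p-values for single probe sets and for array-level values rest on the spread between these samples. P-values for gene lists, gene families and chromosome positions set genes against other genes, and do not measure that spread alone.

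Of 22810 probe sets, 64 AFFX controls were left out of these tests, and fitted apart with adjustment over the 64, and 22746 were kept with no filter on low signals. Gene names came from the platform annotation supplied for this table, updated through Entrez identifiers to NCBI RefSeq names of the TAIR10.1 assembly. Among the tested probe sets 13513 named 1 gene, 503 named several and 8730 were unnamed here; the 13513 covered 13355 different genes, and 13436 of them matched RefSeq. Only probe sets with 1 gene were named, and the probe set with the highest mean over all arrays stood for a gene with several. The files name no genome build, so no coordinates are given, and only the order of genes along chromosomes was used. Probe sets whose identifier ends in s_at can detect several similar transcripts.

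Differences were tested with limma 3.58.1 in R 4.3.3: a mean per genotype was fitted to all 9 arrays (lmFit), the comparisons ebs minus wild type, shl-2 minus wild type and shl-2 minus ebs were drawn from that fit (contrasts.fit), and variances were moderated with eBayes at default settings. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all 22746 probe sets within each comparison, and a probe set was called at an adjusted p under 0.05. Errors of log2 fold changes are limma's moderated standard errors, and errors of group means are SDs. Values at the level of arrays were compared with exact permutation tests, whose smallest p for 3 against 3 is 0.1.

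The samples, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule named EBS, SHL and 8 flowering genes, the 8 highest and 8 lowest log2 fold changes per comparison among called genes whose arrays did not overlap between the groups, the 5 higher and 5 lower shared genes with the largest smaller change, up to 4 members of each list with the smallest p, and up to 4 genes of lowest adjusted p in a region tested. Members of gene families, genes on in a single mutant and transcripts with opposite changes were named after their values were seen.

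Of 394 members of 22 lists, 54 had a named probe set. The 10 lists with at least 3 measured members were tested with limma's camera on 1 probe set per gene with a preset correlation of 0.01, adjusted over the 10 lists, and again with the correlation estimated from the residuals. Another 9 lists had 1 or 2 measured members and 3 had none. In addition, 26 families of at least 10 genes were formed from the letters that open gene symbols and synonyms, plus the genes of the plastid genome, and tested in the same way; these families were chosen after the data were examined. Median, mean and camera direction differed in sign for photosynthesis in ebs, for heat shock, the reference genes and senescence in shl-2, and for floral repressors and the reference genes between the mutants, none of which passed.

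Both mutants are compared with the same wild type arrays. Chance sharing was therefore estimated in 100 simulations in which all arrays, wild type included, were simulated without any effect. In each, both mutants were compared with the same simulated wild type arrays. Chance sharing was also estimated from the product of the list sizes over the number tested.

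Alternatives were a block for the replicate number, median centring, a repeated quantile normalization, removal of the dimmest 30% of probe sets, trended and robust variances, array weights, a fit of only the compared groups, 1 probe set per gene, a 2-fold minimum, an adjusted p under 0.01, an estimated correlation in camera, and leaving out each array in turn. Added after the data were seen were the main axis of within-group variation as a covariate and the same alternatives for the gene families. Also added was the removal of 2 arrays with a low average over the BioB, BioC, BioDn and CreX spike-in probe sets, called the arrays with low spike-in controls.

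The fit was tested on simulated arrays with the wild type means and the moderated spreads of the 22746 probe sets, in which 200 were changed per mutant. For ebs against wild type it recovered 61.2% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and all 66 changes of 2, with 5 unchanged probe sets called. For shl-2 against wild type the shares were 55.2%, 95.5% and 100%, with 7 unchanged probe sets called. For shl-2 against ebs they were 67.9%, 97.8% and 100%, with 18. For ebs against wild type, camera called 5 of 5 simulated lists of 6 genes shifted by 0.6 and 0 of the 15 unshifted lists among 13355 genes. With an estimated correlation it also called 5 shifted and 0 unshifted lists. Genes were simulated independently, so this does not show the error rate for lists whose genes vary together.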

Results

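Transcript levels were measured in whole Arabidopsis thaliana seedlings of the accession Landsberg erecta (Ler), grown for 18 days on solid medium in short days of 8 h light and 16 h darkness. The seedlings were wild type or carried a mutation, ebs or shl-2, in EBS or SHL, genes for related chromatin proteins with roles in the repression of flowering. Each genotype was represented by 3 independent biological samples, each hybridized to its own array, which gave 9 arrays. Every array reported 22810 probe sets, of which 64 were control probe sets, for added spikes and for plant transcripts such as actin and ribosomal RNA, and 22746 were tested. Median log2 signals lay between 6.06 and 6.13. The number of arrays per genotype limits the precision of all values below. Arrays of the same genotype correlated with r = 0.992 to 0.997 and arrays of different genotypes with r = 0.988 to 0.995, across probe sets, which are not independent replicates. The first principal component held 32.2% of the variance and gave scores of -29.6 to -11.5 to the 3 wild type arrays and -0.667 to 17.7 to the 6 mutant arrays.

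The series sets mutants described as lacking EBS or SHL transcript against wild type, so the targeted genes were examined first. SHL, annotated as SHL1, read 7.88, 8.02 and 7.88 in wild type, 8.08, 7.82 and 7.81 in ebs, and 7.46, 6.91 and 6.52 in shl-2. It was lower in shl-2 than in wild type by a log2 fold change of -0.96 (SE 0.19, n = 3, limma adjusted p = 0.0182), and all 3 shl-2 arrays lay below the other 6 arrays. In ebs the log2 fold change was -0.02 (adjusted p = 0.973). The mean signal in shl-2 was 6.96 ± 0.47 (SD, n = 3), and where this probe set lies relative to the mutation was not analysed here. The SHL1 call ended without wild type array 2 (log2 fold change -0.92, limma adjusted p = 0.0772), wild type array 3 (-0.99, 0.0586) or shl-2 array 2 (-0.94, 0.0608), and when only the shl-2 and wild type arrays were fitted (adjusted p = 0.0502). EBS had no named probe set and was not analysed here, and the same holds for the flowering genes FT, TSF, SOC1, FLC, SVP, CO, LFY and AP1.

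In ebs, AGL24, which encodes a MADS-box promoter of flowering, rose from 3.93 ± 0.05 (SD, n = 3) in wild type to 6.0 ± 0.63 in ebs, a log2 fold change of 2.07 (SE 0.25, limma adjusted p = 0.00241). On the chromosome that also carries EBS, AGL24 lies at position 114 among the measured genes counted from EBS. AT3G18330 rose from 2.96 ± 0.23 to 5.90 ± 0.10 (log2 fold change 2.94, SE 0.17, adjusted p = 6.72e-05). Its probe set is of a type that can also detect similar transcripts. Its wild type signal and that of AT1G65760 lay below the lower quartile of wild type means, 3.86, so the sizes of these fold changes depend on the background. AT3G28500, which encodes an acidic ribosomal protein of the P2 type, and AT5G56910 rose by 2.70 (SE 0.21, adjusted p = 0.000299) and 2.50 (SE 0.14, adjusted p = 5.79e-05) on the log2 scale. The expansin-like gene EXLA1 (log2 fold change 1.93, SE 0.21, adjusted p = 0.00163) and EXORDIUM, EXO (1.85, SE 0.18, adjusted p = 0.000944) rose as well. The other named genes among the 8 largest increases were AT1G50040 (log2 fold change 2.37), AT1G31690 (2.35), which encodes a copper amine oxidase, AT2G16005 (2.31), AT3G19680 (2.18) and AT1G65760 (2.15).

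Among named genes, the 8 largest decreases in ebs were smaller, from AT1G20070 (log2 fold change -1.56, SE 0.17, adjusted p = 0.00169) to the organic cation transporter gene OCT5 (-1.08, SE 0.14, adjusted p = 0.00312). Between them lay AT3G56260 (log2 fold change -1.40), AT1G48100 (-1.31), AT1G78170 (-1.30), AT2G15020 (-1.26), AT2G44940 (-1.13) and AT2G27420 (-1.12). In total 726 of 22746 probe sets passed limma's test with Benjamini-Hochberg adjustment in ebs against wild type, 391 higher and 335 lower, and 144 of them changed at least 2-fold, 116 upwards and 28 downwards. Counted by the 1 probe set that stood for each gene, 376 named genes were called, 208 higher and 168 lower. The ebs and wild type arrays did not overlap for any of the 726, nor for 19.9% of all tested probe sets, against the 10% that chance gives with 3 arrays against 3. Of the 16 genes named by size, 11 passed whichever array was left out. AT1G31690 did not pass without wild type array 2 or ebs array 1 (highest adjusted p = 0.062). AT1G48100 and AT2G15020 failed without wild type arrays 2 or 3 or ebs arrays 1 or 3 (highest 0.0913 and 0.0738). AT2G44940 failed without wild type arrays 2 or 3, any ebs array or shl-2 array 1 (highest 0.122), and AT2G27420 without any array other than wild type arrays 2 and 3 (highest 0.152). The total fell to 264 without ebs array 1, 265 without wild type array 2, 306 without ebs array 3 and 416 without wild type array 3.

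**Figure D1:**
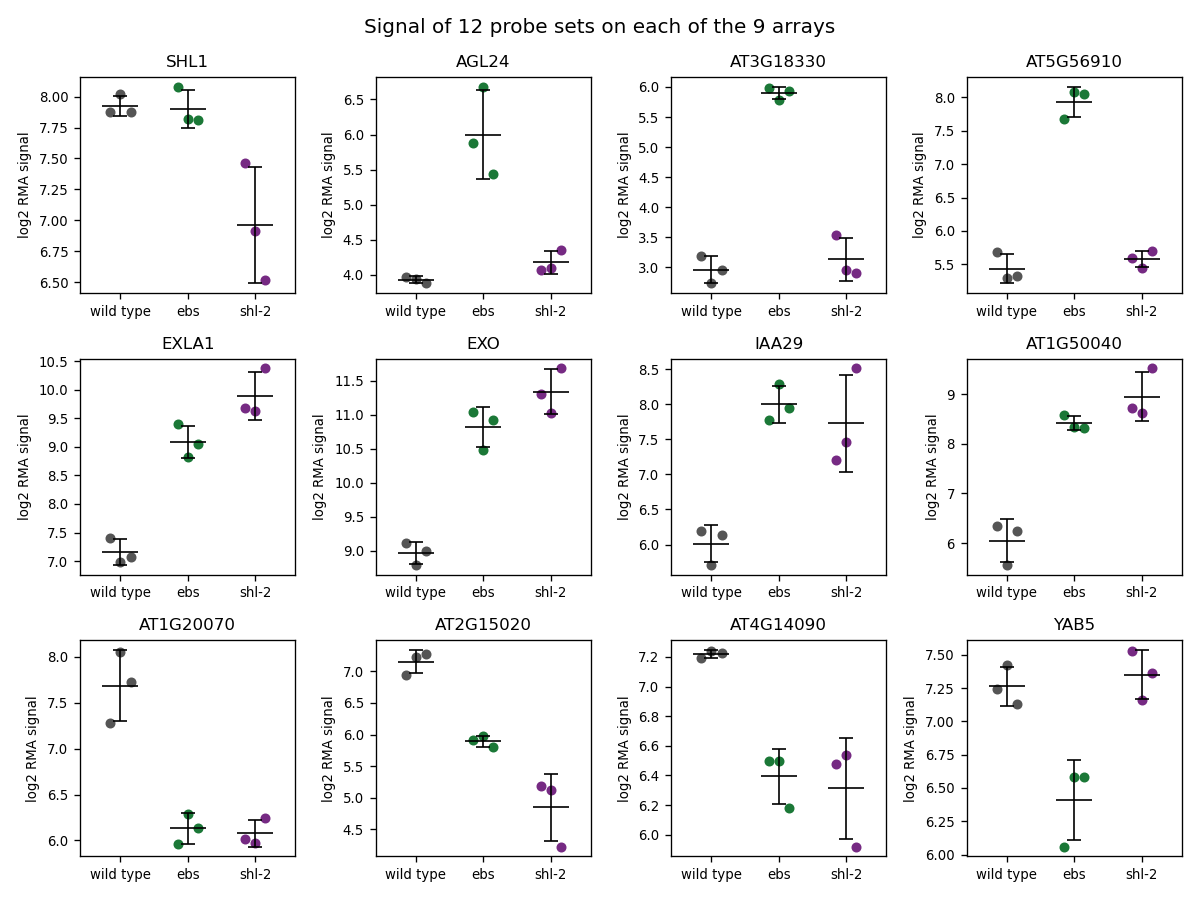
Log2 RMA signal (vertical axes, scaled for each gene) of 12 probe sets on the 3 wild type, 3 ebs and 3 shl-2 arrays (horizontal axes). Points are single arrays, horizontal bars the mean of 3 arrays and whiskers 1 SD. AGL24 stood at 3.93 in wild type, 6.0 in ebs and 4.18 in shl-2 on average, while EXLA1 stood at 7.16, 9.08 and 9.89.

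Among the gene lists fixed before the data were examined, enzymes of flavonoid and anthocyanin synthesis had lower signals in ebs. All 6 measured members had negative log2 fold changes, with a median of -0.58. Over all probe sets 2 passed the test, namely AT4G14090, the anthocyanin 5-O-glucosyltransferase UGT75C1 (log2 fold change -0.83, adjusted p = 0.0216), and the anthocyanin malonyltransferase gene AT5MAT (-0.70, adjusted p = 0.0488). The values were -0.59 for the dihydroflavonol reductase DFR (adjusted p = 0.0857) and -0.58 for the flavonoid glucosyltransferase UGT78D2 (adjusted p = 0.0509). The list as a whole moved down relative to other genes (camera adjusted p = 5.27e-05, but adjusted p = 0.102 with an estimated correlation), and 5 members passed when adjusted over the list alone. The early auxin response list moved up (camera adjusted p = 0.00151, but adjusted p = 0.0596 with an estimated correlation), with 2 of 4 measured members passing over all probe sets and also 2 when adjusted over the list alone: the auxin-inducible repressor IAA29 (log2 fold change 1.99, adjusted p = 0.00721) and the auxin-conjugating enzyme WES1 (0.71, adjusted p = 0.0306). GH3.3 read 0.65 (adjusted p = 0.493) and GH3.1 0.02 (adjusted p = 0.942). The floral promoter list moved up (camera adjusted p = 0.00109, but adjusted p = 0.0596 with an estimated correlation), with AGL24 as the single member of 4 past the test over all probe sets and 2 when adjusted over the list alone. AGL19, FD and AGL42 had log2 fold changes of 0.33, 0.11 and 0.11. In leave-one-out fits, AT4G14090 lost its call without wild type arrays 2 or 3 or ebs arrays 1 or 3 (highest adjusted p = 0.0909), WES1 without these or shl-2 array 2 (0.108) and AT5MAT without any array other than wild type array 1 and shl-2 array 3 (0.162), whereas AGL24 and IAA29 kept theirs.

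The other 7 lists with at least 3 measured members did not pass in ebs, with camera adjusted p from 0.0867 for senescence to 0.819 for the reference genes, and 4 of the 10 lists had an unadjusted p under 0.05. These lists were floral repressors, gibberellin metabolism and signalling, photosynthesis, cold, drought and abscisic acid, heat shock, senescence and reference genes. Single members that passed were SMZ, an AP2-type repressor of flowering, at a log2 fold change of -0.62 (adjusted p = 0.0491), and the dehydrin gene COR47 at 0.41 (adjusted p = 0.037). SMZ lost its call without any array other than ebs array 1 and shl-2 array 3, and COR47 without any wild type or ebs array, with highest adjusted p of 0.166 and 0.132. When adjusted over the list alone, 2 cold, drought and abscisic acid genes were higher, 1 senescence gene was higher and 1 floral repressor was lower. Photosynthesis transcripts differed little, from -0.06 for LHCB4.1 to 0.09 for PSAN. Of 26 gene families defined by shared symbols, the plastid-encoded genes moved down in ebs (camera adjusted p = 0.00471, but adjusted p = 0.589 with an estimated correlation). Of its 69 measured members 52 had negative values, the median log2 fold change was -0.13, and 1 member passed over all probe sets. The mean signal over plastid probe sets was 10.30 ± 0.12 (SD, n = 3) in wild type and 10.16 ± 0.05 in ebs (two-sided exact permutation p = 0.2, where 0.1 is the smallest that 3 against 3 arrays can give). The family did not pass without wild type array 2 (adjusted p = 0.135), which left 0 families; without wild type arrays 1 or 3 or ebs arrays 2 or 3 there were 4, 6, 2 and 2.

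In shl-2, AT1G50040 rose from 6.05 ± 0.43 (SD, n = 3) to 8.95 ± 0.49 (log2 fold change 2.90, SE 0.25, limma adjusted p = 0.000305). EXLA1 rose by 2.73 on the log2 scale (SE 0.21, adjusted p = 0.000302), EXO by 2.37 (SE 0.18, adjusted p = 0.000302) and XTH33, a xyloglucan-modifying enzyme gene, by 2.21 (SE 0.32, adjusted p = 0.00397). AT2G25510 (log2 fold change 2.57), AT3G19680 (2.49), AT2G27080 (2.04) and AT2G47440 (1.92) completed the 8 largest increases among named genes. The largest decrease of a named gene was that of AT2G15020, from 7.15 ± 0.18 to 4.85 ± 0.54 (log2 fold change -2.30, SE 0.22, adjusted p = 0.000399). AT3G52740, which encodes BIC1, an inhibitor of the cryptochrome blue-light receptors, fell by 1.53 on the log2 scale (SE 0.16, adjusted p = 0.00081). Other large decreases of named genes were those of AT1G48100 (log2 fold change -1.81), AT2G19650 (-1.63), AT1G20070 (-1.61), the glycosyltransferase gene UGT73C1 (-1.51), AT2G27420 (-1.50) and AT5G42760 (-1.43).

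In shl-2 against wild type, 1235 of 22746 probe sets passed limma's test with Benjamini-Hochberg adjustment, 555 higher and 680 lower. Of these, 200 changed at least 2-fold, 127 upwards and 73 downwards, and 593 were the probe sets that stood for a named gene, 257 higher and 336 lower. Arrays of the groups did not overlap for 1234 of the calls, nor for 20.5% of all tested probe sets, against a chance share of 10%. Of the 16 genes named by size, 15 passed whichever array was left out. The exception was AT2G25510, which read 7.06, 4.34 and 7.21 on the shl-2 arrays and failed without any array other than ebs array 2 and shl-2 array 2 (highest adjusted p = 0.125). The total fell to 677 without wild type array 2 and to 803 without wild type array 3.

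The flavonoid and anthocyanin list was also lower in shl-2 (camera adjusted p = 5.99e-05, but adjusted p = 0.242 with an estimated correlation). All 6 members had negative values with a median log2 fold change of -0.57. AT4G14090 (log2 fold change -0.91, adjusted p = 0.00796) and UGT78D2 (-0.90, adjusted p = 0.00435) passed over all probe sets, and 5 members passed when adjusted over the list alone. AT5MAT (-0.54), DFR (-0.49) and the anthocyanin glycosyltransferase gene UF3GT (-0.60) did not pass over all probe sets. Without wild type array 1 or shl-2 array 3 the lists that passed numbered 2. The other 9 lists did not pass, with camera adjusted p from 0.0748 for the early auxin response to 0.986 for senescence, and 2 of the 10 had an unadjusted p under 0.05. IAA29 alone among the 4 auxin genes passed over all probe sets and when adjusted over the list alone (log2 fold change 1.71, adjusted p = 0.00811). COR47 passed at 0.59 (adjusted p = 0.00424), the gibberellin receptor gene GID1C passed at -0.36 (adjusted p = 0.044, lost in each of the 9 leave-one-out fits, highest adjusted p = 0.128), and both passed within their lists alone, as did 2 floral repressors, which were lower. AGL24 had a log2 fold change of 0.25 (adjusted p = 0.666).

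Of the 26 families, 6 passed in shl-2. The xyloglucan endotransglucosylase/hydrolase family XTH moved up (camera adjusted p = 0.0007, but adjusted p = 0.405 with an estimated correlation). Of its 10 measured members 4 were higher and none lower, among them XTH33, XTH16 (log2 fold change 0.98, adjusted p = 0.00284) and EXGT-A3 (0.91, adjusted p = 0.000744), together with XTH19 (0.91, adjusted p = 0.019), which lost its call without wild type arrays 1 or 3 or shl-2 arrays 1 or 3 (highest 0.078). The UGT glycosyltransferase family moved down (camera adjusted p = 0.00439, but adjusted p = 0.482 with an estimated correlation), with 9 of 47 members lower and none higher, including UGT73C1, UGT78D2 and UGT76E11 (log2 fold change -0.88, adjusted p = 0.00504). The BZIP transcription factors moved up (camera adjusted p = 0.0408, but adjusted p = 0.482 with an estimated correlation, 0.0627 with dim probe sets left out and 0.0557 when only the shl-2 and wild type arrays were fitted). BZIP61 (log2 fold change 1.24, adjusted p = 0.00422), BZIP34 (1.07, adjusted p = 0.00335) and BZIP53 (0.82, adjusted p = 0.00331) were higher and the other 19 of 22 did not pass. The tetraspanin genes counted under both of their symbols, TETRASPANIN and TET, moved up (camera adjusted p = 0.0156 and 0.0344, but adjusted p = 0.482 for both with an estimated correlation), with TET8 and TET10 passing. TET8 lost its call without wild type arrays 2 or 3, ebs array 1 or shl-2 arrays 1 or 3 (highest adjusted p = 0.115), and TET10 without wild type arrays 1 or 2, ebs arrays 1 or 3 or shl-2 array 3 (0.116). The plastid-encoded genes moved down (camera adjusted p = 0.0007, but adjusted p = 0.486 with an estimated correlation), with 54 of 69 values negative and 4 members lower, such as psbB (log2 fold change -0.84, adjusted p = 0.00537) and psbD (-0.59, adjusted p = 0.00947), both for photosystem II proteins. The plastid mean was 10.14 ± 0.12 (SD, n = 3) in shl-2 against 10.30 ± 0.12 in wild type (two-sided exact permutation p = 0.3). In ebs these families other than the plastid genes had the same camera direction without passing. Camera adjusted p there was 0.052 for XTH, 0.0721 for BZIP and TETRASPANIN, 0.125 for TET and 0.076 for UGT. None passed between the mutants (camera adjusted p = 0.0691 for XTH, 0.185 for UGT, 0.694 for BZIP, 0.684 for TETRASPANIN and TET). Their shifts are thus not shown to be particular to shl-2. In shl-2, XTH passed whichever array was left out, whereas single arrays ended the other calls. Without wild type array 1, 3 families passed and UGT (adjusted p = 0.0705), TETRASPANIN (0.0708) and TET (0.123) did not. Without shl-2 array 3 only XTH, 1 family, passed, with the plastid genes at 0.105, UGT and TETRASPANIN at 0.0773, TET at 0.105 and BZIP at 0.094. Without wild type array 2 the plastid genes (0.0714), TET (0.0812) and BZIP (0.083) did not pass, nor did BZIP without wild type array 3 (0.0795) or ebs array 2 (0.0519).

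The direct comparison of shl-2 with ebs asked where the mutants differed from each other. AT3G28500 and AT3G18330 were lower in shl-2 than in ebs by log2 fold changes of -2.78 (SE 0.21, limma adjusted p = 0.000378) and -2.77 (SE 0.17, adjusted p = 6.53e-05), and AGL24 by -1.82 (SE 0.25, adjusted p = 0.0101). AT1G31690 (log2 fold change -2.45), AT1G65760 (-2.41), AT5G56910 (-2.36), AT5G66970 (-1.90) and AT1G03710 (-1.64) were the other named genes among the 8 lowest. Signals of AT3G18330, AT1G65760, AT5G66970 and AT1G03710 lay below the lower quartile in shl-2, so the sizes of these differences depend on the background. Higher in shl-2 than in ebs were AT1G42705 (log2 fold change 2.06, SE 0.17, adjusted p = 0.000661), AT3G27473 (1.44), AT3G30200 (0.99), AT1G61100 (0.94), AT1G36940 (0.88), AT4G39420 (0.82) and AT5G61570 (0.78). YAB5, a YABBY transcription factor gene of leaf polarity, was 7.26 ± 0.15 (SD, n = 3) in wild type, 6.41 ± 0.30 in ebs and 7.35 ± 0.19 in shl-2 (shl-2 minus ebs 0.94, SE 0.15, adjusted p = 0.0227).

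In all, 175 probe sets differed between shl-2 and ebs, 61 higher and 114 lower in shl-2, and 84 of them stood for a named gene. Of the 45 that differed at least 2-fold, 5 were higher and 40 lower in shl-2. The arrays of the mutants did not overlap for any of the 175, nor for 14.0% of tested probe sets, where chance gives 10%. Of the 10 lists, the floral promoters were lower in shl-2 than in ebs (camera adjusted p = 0.0328), with AGL24 the single member of 4 past the test over all probe sets and 2 past it when adjusted over the list alone; the list gave adjusted p = 0.245 with an estimated correlation. Adjusted over the list alone, 1 early auxin response gene was lower, 1 floral repressor was higher and 1 lower. The other 9 lists had camera adjusted p from 0.0643 for senescence to 0.993 for the reference genes. The expansin family EXP was lower in shl-2 (camera adjusted p = 0.0402) with 8 of 10 values negative and no member past the test over all probe sets, and gave adjusted p = 0.758 with an estimated correlation and adjusted p = 0.096 after a repeated quantile normalization. The floral promoter call ended without wild type arrays 1 or 3 (adjusted p = 0.0523 and 0.0633) or shl-2 arrays 1 or 3 (0.0792 and 0.083), and the EXP call without wild type array 3 (0.0578), ebs array 2 (0.227) or shl-2 arrays 1 or 3 (0.108 and 0.0703). The AGL24 call ended without shl-2 array 1 (log2 fold change -1.77, adjusted p = 0.0511) and when only the shl-2 and ebs arrays were fitted (adjusted p = 0.0575; range over all settings 0.000405 to 0.0575). Of the genes named by size, 10 of the 16 passed whichever array was left out, and 5 other calls were lost. They were AT1G31690 without wild type array 2, any ebs array or shl-2 arrays 1 or 2 (highest adjusted p = 0.113), AT1G36940 without ebs arrays 1 or 3 or shl-2 arrays 1 or 2 (0.066), AT1G61100 without any ebs array or shl-2 array 1 (0.0709), AT5G61570 without any mutant array (0.143) and YAB5 without ebs array 1 or shl-2 arrays 1 or 3 (0.0923). The total fell to 64 without ebs array 1, 84 without shl-2 array 1, 98 without ebs array 3 and 104 without shl-2 array 2.

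**Figure D2:**
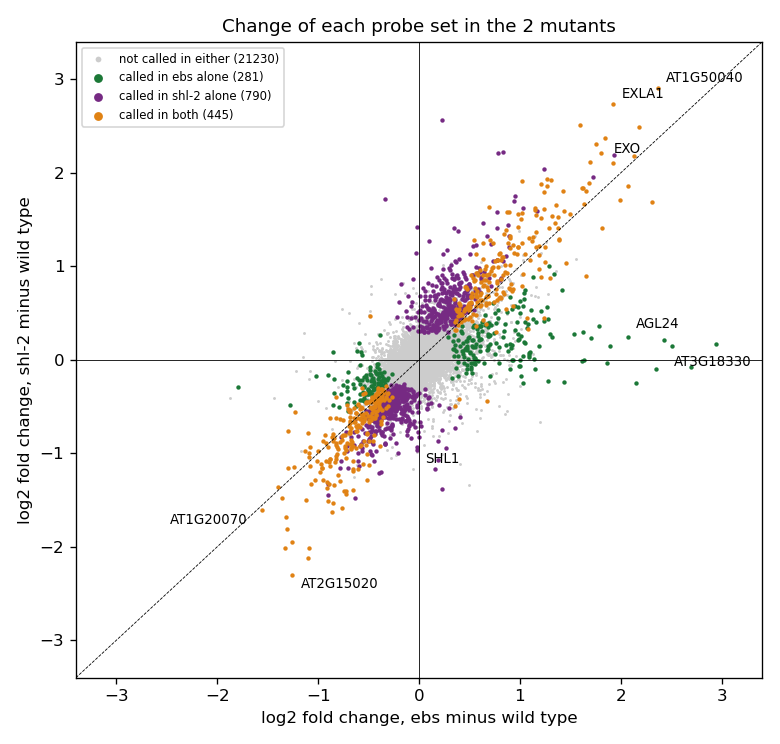
Log2 fold change against wild type in ebs (horizontal axis) and in shl-2 (vertical axis) of the 22746 tested probe sets, coloured by whether limma's test passed in ebs, in shl-2, in both or in neither, with the diagonal of equal change dashed. The 445 probe sets called in both mutants lie mostly along the diagonal, and AGL24 and AT3G18330 lie to the right, near no change in shl-2.

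Many transcripts changed alike in both mutants. AT1G50040, AT3G19680, EXLA1, EXO and IAA29 had the largest increases common to both among named genes, and AT1G20070, AT3G56260, AT1G48100, AT2G15020 and AT2G27420 the largest common decreases. EXO, for example, read 8.97 ± 0.16 (SD, n = 3) in wild type, 10.81 ± 0.30 in ebs and 11.34 ± 0.33 in shl-2, and AT3G56260 read 6.05 ± 0.19, 4.65 ± 0.23 and 4.69 ± 0.23. Probe sets called in both mutants in the same direction numbered 441, with 214 higher and 227 lower, whereas lists of these sizes drawn independently would share 9.54 and 10. The simulations described next shared 0.01 on average and 1 at most. They held no change in either mutant, so their shared count was bound to be small. It does not show how many shared calls the common controls add. The shared probe sets made up 54.7% of the higher and 67.8% of the lower calls in ebs. Across all probe sets, which are not independent replicates, log2 fold changes in ebs and shl-2 correlated with r = 0.688, against 0.499 on average in 100 simulations. In these, all arrays were simulated without any effect, and both mutants were compared with the same simulated wild type arrays. The covariance was 0.0414 against 0.00798 simulated, a difference of 0.0335, and 72.6% of probe sets had the same sign against 66.7% simulated. The 3 wild type arrays are too few to be divided into parts of at least 2, so part of the excess may come from the shared controls. The shared total fell to 155 without ebs array 1, 158 without wild type array 2, 174 without ebs array 3 and 252 without wild type array 3.

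Most calls in a single mutant came without a called difference between the mutants. Of 281 probe sets called in ebs but not in shl-2, 67 differed directly (23.8%), and of 790 called in shl-2 but not in ebs, 64 did (8.10%). Over all tested probe sets 175 of 22746 differed directly, so both shares lay above the general share. A difference that did not pass is not shown to be absent. The arrays carry 6 pairs of 3' and 5' control probe sets, 2 each for actin, GAPDH and ubiquitin, and 1 of the 6 separated the mutants from wild type. In that ubiquitin pair the 3' minus 5' log2 signal was 1.17 to 1.41 in wild type and 1.43 to 1.48 in the mutants, whereas in the other ubiquitin pair it was 0.55 to 0.82 and 0.54 to 0.76. An actin pair separated ebs alone, at 1.56 to 1.58 against 1.43 to 1.54 in wild type, and the other actin pair did not (3.21 to 3.27 against 3.25 to 3.52). Averaged over 1 pair for each of the 3 transcripts it was 1.14 ± 0.10 (SD, n = 3) in wild type, 1.21 ± 0.02 in ebs and 1.29 ± 0.06 in shl-2 (two-sided exact permutation p = 0.4 for ebs and 0.2 for shl-2 against wild type).

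The remaining lists had 1 or 2 measured members each and were not tested as groups. They covered the photoperiod pathway and clock (GI and AT1G69570), floral organ identity (UFO), histone deacetylation and methylation (HDA15 and LDL2), salicylic acid defence (SAG101), jasmonate and wounding (PDF1.2 and THI2.1), glucosinolate synthesis (BCAT4 and AOP3), cell division and the shoot meristem (CLV3), iron uptake and storage (PYE and BHLH101) and root markers (PYK10 and EXPA7). None of these 15 genes passed limma's test in any comparison, with lowest adjusted p of 0.0767 in ebs, 0.089 in shl-2 and 0.104 between the mutants; at an unadjusted p under 0.05 there were 4, 1 and 3 of them. Their log2 fold changes ran from -0.80 (BHLH101) to 0.58 (PDF1.2) in ebs and from -1.0 (THI2.1) to 0.52 (PDF1.2) in shl-2. GI, a clock-regulated gene of the photoperiod pathway, read 0.03 in ebs and -0.11 in shl-2. Seed maturation, Polycomb group and phosphate starvation genes had no named probe set and were not analysed here.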

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

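The test of RNA integrity below was chosen only after its result had been seen, and so were the tests over all 6 combinations of window and comparison, the comparison of all control pairs and the positions of AGL24 and AGL19. The test of the within-group axis replaced one whose outcome the centring fixed, with its bounds written before its value was seen. The gene families and the settings for low spike-in arrays and for the within-group axis were chosen after the data had been seen.

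Of the probe sets called in both mutants, 4 changed in opposite directions. The differences between the mutants given for them are sums of the called changes for which they were chosen, so their adjusted p adds no further evidence. AT1G01390 was higher in ebs (log2 fold change 0.67, limma adjusted p = 0.00654) and lower in shl-2 (-0.44, adjusted p = 0.0293), with shl-2 minus ebs at -1.11 (adjusted p = 0.000784). AT3G47540 was higher in ebs (0.40, adjusted p = 0.0183) and lower in shl-2 (-0.42, adjusted p = 0.00822), with a difference of -0.82 (adjusted p = 0.000784). The unnamed probe set 250566_at behaved likewise, at 0.35 in ebs and -0.49 in shl-2 (difference -0.84, adjusted p = 0.000899), and the unnamed probe set 245138_at the other way, at -0.49 in ebs and 0.47 in shl-2 (difference 0.96, adjusted p = 0.000661). The call in ebs ended without any array other than shl-2 array 3 for 250566_at (highest adjusted p = 0.125), without wild type arrays 2 or 3 or ebs arrays 1 or 3 for AT3G47540 (0.0803) and without wild type array 2 or ebs arrays 1 or 3 for 245138_at (0.0578). The call of AT1G01390 in shl-2 ended without wild type arrays 2 or 3, ebs array 1 or any shl-2 array (0.0915). No explanation was tested for these.

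The 441 probe sets changed alike in both mutants were weighed against 3 technical explanations. In 100 simulations with shared wild type arrays and no effect, the covariance of log2 fold changes was at most 0.00927. The observed covariance was 0.0414. However, the simulated noise was independent between probe sets, whereas 44.1% of the measured within-group variance lay on 1 axis. The simulated range may therefore be too narrow, and this comparison cannot decide how much of the sharing comes from the wild type arrays. Among 100 splits of the 9 arrays into 3 groups of 3 only the real one, 1 split, gave 441, and the highest other gave 82. The other splits mix genotypes, which adds differences between genotypes to the spread within groups and lowers the calls. The splits thus bear on whether the genotypes differ, and cannot tell whether the mutants share changes. A displacement of the mutants along the main axis of variation within genotypes, which held 44.1% of the within-group variance, stays open, because across the shared probe sets the mean change and the loading on that axis correlated with r = 0.426, against 0.125 over all tested probe sets. A difference in RNA integrity stays open too, since the 3' minus 5' signal separated the mutants from wild type for 1 of 3 control transcripts in the pairs first chosen and for 1 of all 6 pairs, with overlap in the other pair of that transcript, ubiquitin, so these and an effect common to EBS and SHL may all contribute and cannot be told apart.

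The position of called genes along the chromosomes was weighed as a second pattern, since a linked segment of another origin could alter genes beside a mutated locus. In ebs, 12 of the 200 measured genes nearest EBS were called (6%) against 2.77% elsewhere, an odds ratio of 2.24 (95% interval 1.13 to 4.06, Fisher's exact p = 0.0143, adjusted over both mutants 0.0286), which is what such a segment would give; AT4G23680 (log2 fold change 1.24), AT4G23870 (1.08), AT4G24060 (0.84) and IQD22 (-0.48) had the lowest adjusted p, that of IQD22 passing except without ebs array 1 (0.0504). Of the 12, 6 also passed in shl-2 in the same direction, namely AT4G24060, IQD22, AT4G19890, AT4G21890, AT4G22212 and AT4G22820. Among all ebs calls 54.7% of the higher and 67.8% of the lower were shared in this way, so these 6 do not argue against a segment. Only 1 of the 200 differed directly between the mutants (odds ratio 0.79, 0.02 to 4.59), and this interval includes 2.24, so it cannot decide either. AGL24, called in ebs and in the direct comparison, lies at position 114 from EBS, just outside the 100 measured genes on either side. AGL19 (log2 fold change 0.33, limma adjusted p = 0.0625) lies at position 41, inside them. Adjusted over all 6 combinations of window and comparison, the Fisher p for ebs around EBS was 0.0859. A linked segment around EBS thus stays open. Around SHL, 11 of 154 genes were called in shl-2 (odds ratio 1.68, 0.81 to 3.11, Fisher's exact p = 0.11), led by EXLA2, AT4G39780, AT4G38810 and AT4G39420. Across the genome, called genes formed 1 neighbouring pair between the mutants, AT1G31690 and AT1G31710 (permutation p = 0.406), 8 pairs in ebs against 10.5 in random draws (p = 0.826) and 27 in shl-2 against 25.9 (p = 0.438), none of which shows segments elsewhere or excludes small ones, and local effects of the mutated genes themselves remain possible and untested.

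The lower plastid-encoded transcripts were weighed as the pattern left. A share of plastid RNA that varies from array to array may account for them: the plastid mean ranged over 0.236 log2 units among the 3 wild type arrays, which exceeds the differences of 0.15 for ebs and 0.16 for shl-2. It ranged over 0.217 among the shl-2 arrays, but over 0.106 among the ebs arrays, which is below the difference for ebs. The biological explanation, an effect of the genotypes, was not tested apart from this and stays open.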

How the results depend on the processing

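The within-group axis as a covariate, the omission of arrays with low spike-in controls and all settings of the gene families were chosen only after the data had been seen. Among the named genes and the lists and families that passed, no called value reversed under any alternative. For single genes this outcome was nearly fixed in advance. Arrays of the compared groups did not overlap for nearly all calls, so omitting 1 array could not turn the sign of those calls. The block, the trended variances and the covariate leave fold changes as they are. Of 6474 recomputed values of named genes 6075 kept their direction and side of the threshold or were uncalled throughout, 311 lost their call, 88 gained one, and 195 uncalled values changed sign. The 6075 thus do not give the share of calls that were kept. Median centring, a repeated quantile normalization, removal of the dimmest 30%, and trended and robust variances left the 3 gene counts and the overlap within 1.5 times, and 93.9% of the shared probe sets stayed shared after median centring. Array weights gave 1129 calls in ebs and 364 between the mutants. Fitting only the compared groups gave 112 between the mutants and ended the SHL1 call (log2 fold change -0.96, limma adjusted p = 0.0502, range over its settings 0.00279 to 0.0772). Counts with 1 probe set per gene were 370 in ebs, 568 in shl-2, 84 between the mutants and 211 shared, because fewer features were tested; with a 2-fold minimum 144, 200, 45 and 74; at an adjusted p under 0.01 212, 530, 51 and 122.

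With the within-group axis as a covariate, calls rose to 1329 in ebs, 1860 in shl-2, 453 between the mutants and 757 shared. That axis sums to 0 within each genotype, so it leaves fold changes as they are and only lowers the residual variance. Without the 2 arrays with low spike-in controls the gene counts (667, 968 and 126) and the overlap (342) stayed within 1.5 times.

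Leaving out single arrays gave 264 to 838 calls in ebs, 677 to 1229 in shl-2, 64 to 190 between the mutants and 155 to 459 shared, and SHL1 at -1.21 to -0.74; lists ran from 3 to 4, 1 to 2 and 0 to 2, and families from 0 to 6, 1 to 7 and 0 to 2 for ebs, shl-2 and the direct comparison. With the estimated correlation in limma's camera 0 lists and 0 families passed in each comparison; at an unadjusted p under 0.05 lists numbered 3, 2 and 1 and families 1, 2 and 1. Otherwise lists in shl-2 numbered 2 in place of 1 with dim probe sets left out, array weights, the covariate or without the low spike-in arrays, and lists between the mutants 2 in place of 1 with median centring, repeated quantile normalization, array weights or the covariate and 0 in the 2-group fit and without the low spike-in arrays. Families in ebs numbered 6 in place of 1 with dim probe sets left out and 2 with trended variances, array weights or without the low spike-in arrays; in shl-2 1 in place of 6 without those arrays; between the mutants 2 in place of 1 with dim probe sets left out or trended variances and 0 with repeated quantile normalization, array weights, the 2-group fit or without the low spike-in arrays. Apart from the counts that follow from a stricter rule or fewer features or arrays, the cause was not tested.

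With the replicate number as a block, calls were 898, 1402, 248 and 542 shared, SHL1 kept its call (adjusted p = 0.00907), lists numbered 2 in shl-2 and 2 between the mutants, and families 2 in ebs and 2 between the mutants. The main fit did not pair samples by number. Of 9 same-number pairs of arrays, 7 had deviations correlating over 0.1 (-0.29 to 0.46), while pairs with different numbers ran from -0.54 to 0.46. Of 9 arrays, 5 correlated best with their own number. A batch shared by equal numbers therefore stays open. Signals near the lower quartile, such as AGL24 in wild type, limit how well low transcripts can be measured.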

Other observations

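The comparisons of genes near the floor and of the size of the shared change were chosen only after the data had been seen, and so were the families. Some genes had signals near the floor outside 1 mutant. With a limit at the lower quartile of wild type means, 3.86 on the log2 scale, and at the same quartile of the other mutant, 5 genes lay below it in wild type and shl-2 yet were at least 2-fold higher in ebs than in wild type and called in the direct comparison as well: AT3G18330, AT1G65760, AT5G66970 (log2 fold change in ebs 1.86), AT1G03710 (1.64) and AT4G05470 (1.09). The reverse pattern, on in shl-2 alone, held for 2 probe sets, 1 of them named, AT3G27473, with a log2 fold change of 1.42 in shl-2 and -0.02 in ebs. AGL24 lay just above the limit in wild type, at 3.93. The difference between 5 and 2 was not tested.

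The size of the shared change was compared between the mutants. Averaged over the 441 shared probe sets, with each change counted in its own direction, the arrays of ebs had moved from wild type by 0.77 ± 0.03 (SD, n = 3) and those of shl-2 by 0.90 ± 0.10 on the log2 scale. The difference was 0.13 (two-sided exact permutation p = 0.1, the smallest that this test can give with 3 against 3 arrays, so it could not decide). The 441 were chosen as called in both mutants on these same arrays, so a move from wild type was bound to appear. Both averages may therefore be too large. Of the 441, 314 (71.2%) had the larger change in shl-2, and 19 passed the direct test between the mutants. EXLA2, an expansin-like gene, rose by 1.27 in ebs and 1.86 in shl-2.

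With 3 arrays against 3, only 10 splits exist, too few for a share under 0.05. For ebs against wild type the real split gave 726 probe sets and the highest other 2, for shl-2 against wild type 1235 and 0, and for shl-2 against ebs 175 and 0; in each case 1 split, the real one, reached the real count. For gene lists, the real counts of 3, 1 and 1 compare with highest others of 1, 2 and 3, and were reached by 1, 4 and 6 splits. For families, the real counts of 1, 6 and 1 compare with highest others of 4, 6 and 3, and were reached by 5, 2 and 10 splits.

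The control probe set for U12639 read 4.16, 4.59 and 4.70 in shl-2, 4.03, 3.48 and 3.51 in wild type and 3.69, 3.63 and 3.60 in ebs (log2 difference 0.81 in shl-2, adjusted p = 0.107 from a separate limma fit to the 64 controls, adjusted over these alone). Hybridization spikes averaged over the BioB, BioC, BioDn and CreX probe sets were 9.02 on ebs array 2 and 9.20 on shl-2 array 3, below the 9.40 to 9.70 of the other arrays. A second group of probe sets for these spikes, r2, was left out of this average. There ebs array 2 was not the lowest ebs array for bioB, bioC or bioD (bioC-5 9.64 against 9.36 and 9.58), but it was for cre (cre-3 13.33 against 13.41 and 13.43). In the same group shl-2 array 3 was the highest shl-2 array for bioC-5 (9.45) and the lowest for bioD-5 (10.52). The low averages thus depend on the probe sets chosen.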
